A study of Homo sapiens with 64 samples.

How the data were processed

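RNA was measured by paired-end sequencing of libraries made, per the labels' protocols, with a stranded kit that selects polyadenylated RNA, from 64 human small cell lung carcinoma xenografts grown in NSG mice. Per the submitters' processing notes, STAR was the aligner and hg19 the genome build. Their versions, the counting tool, the gene annotation, any scaling step and the handling of mouse reads are not given in the sources used here, so an unknown share of reads from mouse cells may lie in conserved human genes.

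The authors deposited 2 tables of log2 values. In the first, values are log2(TPM + 1) for 60596 Ensembl identifiers in 64 libraries, since 2 raised to each value, minus 1, summed to between 997298 and 999709 TPM per library. The design had assumed TPM on a linear scale, so the deposited log2 values were used as they stood and returned to TPM wherever a level or a rescaling was needed. In the second, deposited for 25455 gene symbols, values are log2 of scaled counts plus 8. There, the scaled count of a gene was a whole multiple of a step fixed for each library, within a tolerance of 0.1, in 100% of the low values of all 63 libraries used, and dividing by that step returned whole reads. Scaled totals were nearly equal, at a median of 15.8 M (M for mega). Of the columns in the second table, 1 was left out because its name matched no sample's label, and 1 CCX tumour therefore had no recovered reads.

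Groups were taken from the labels: CBX_P1 with 58 first-passage tumours, CBX_P2 with 2 second-passage tumours and CCX_P1 with 4 first-passage tumours. The labels do not say what the title prefixes CBX and CCX mean, and the prefix was treated as a possible batch. Among the CBX titles, 3 pairs shared a number and differed in a final letter. Correlations across tumours therefore used 61 tumours, 1 per prefix and number, except those of the principal components. Components of the TPM values and their correlations used all 64 libraries. In addition, 1 CBX_P1 and 1 CCX_P1 tumour (CCX_P1 replicate 4) share a number under different prefixes. The labels do not say whether they are linked, and they were kept as separate tumours and left out of the test of pairs. All libraries carry the same replicate number in the labels, and replicates are named here by their order within a group. Nothing in the labels says which tumours came from separate patients, so p-values measure the spread between these tumours.

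Genes were named through a table of identifiers and symbols, which matched 99.5% of the TPM table's identifiers. All Y-linked genes and XIST were left out of every step. A gene was tested if its TPM was at least 1 in at least 2 libraries, which left 26610 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(TPM + 1) in a single fit of all 64 tumours, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on that log2(TPM + 1) scale, which understates the change of low genes. The same fit without groups, on the mean of a list of 25 neuroendocrine genes, tested which other genes moved with that mean. Before the data were examined, 14 lists of gene groups, 9 lists of markers of other cell types, a panel of 30 genes and 30 relations between measures were fixed. Lists were compared between groups with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. A list's value in a tumour was the mean of log2(TPM + 1) over its measured members, without any gene shared with the other measure of a relation.

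Correlations are Pearson's r and Spearman's rho with two-sided p-values from 100000 permutations (exact below 10 tumours), adjusted over all values computed in the same family. A measure counted as clustered when a mixture of 2 normal distributions (mclust 6.1.1) had a BIC better by over 10 and an Ashman's D over 2. Correlations were then given only within joint clusters of at least 6 tumours, and r was computed again without the 2 tumours farthest from the median of the first measure. Levels, correlations, principal components, permutations and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

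Genes to be named were set in advance. For the group comparisons they are the 10 with the largest positive and the 10 with the largest negative log2 change among those past the threshold. For the neuroendocrine association they are the 12 of highest and the 12 of lowest moderated statistic, for variability the 30 of highest variance, and for each principal component the 8 of largest loading on either side. Ribosomal, histone, small RNA, mitochondrial and immunoglobulin V, D and J genes, and genes without a symbol in the deposited table, were counted but not named. The immunoglobulin exclusion was not in the rule set in advance. The same naming rule, with that exclusion, picked the genes named from rescaled fits. Other members of the lists and the panel, immunoglobulin genes and defensins were named after their values were seen, to describe their group.

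The values showed 2 kinds of library that no label mentions, separated by the share of TPM in 2 abundant noncoding RNAs, 7SK and 7SL. A boundary of 10% of TPM was set after seeing this. Each comparison was therefore repeated with library type as a term of the fit, within each type where it held enough libraries, and with TPM rescaled to a fixed total over nuclear protein-coding genes, that of a full TPM table ("rescaled TPM" below). These alternatives, limma-voom on the recovered reads, and fits without 1 library with few detected genes were chosen after seeing the data. Alternatives written before the data were examined were another pseudocount, 2 other filters, the deposited log counts, quantile and median-of-ratios scaling, robust variance moderation, other sets of tumours, a fibroblast covariate and leaving out each replicate of the small groups.

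The fits were tested on simulated data with 100 genes changed by 2 and 100 by 4 on the log2 scale among 26610, either without library types or with the type differences measured in CBX_P1. Without library types, a log2 change of 4 was recovered for 68% of genes in 2 against 58 tumours and for 92% in 4 against 58, and a change of 2 for 9% and 36%. With library types simulated and no term for them, 30 unchanged genes were called in the passage comparison, and with the term 7 were. The regression recovered 94.5% of 200 genes with a slope of 1. It was simulated for 61 tumours without library types, with a covariate drawn at random. The fit set in advance held 35 tumours of both library types, so that share does not carry over to it. In all simulations the changed genes had a mean above 1 on the log2 scale, so recovery nearer the floor was not tested. With 2 second-passage libraries of 1.86 M and 5.43 M reads, a gene listed at 0 there was below the level that these depths resolve, and its absence is not shown.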

Results

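Gene expression was profiled in 64 xenografts of small cell lung carcinoma, a neuroendocrine lung cancer, each grown from human tumour tissue in NSG mice, which lack mature T, B and NK cells of their own. There were 58 first-passage tumours with titles starting CBX, 2 second-passage tumours with the same prefix, and 4 first-passage tumours with titles starting CCX. Reads recovered from the deposited log counts (M for mega) ranged from 1.86 M to 58.6 M per library, with a median of 19.9 M over 63 libraries. Between 5127 and 17504 genes reached a TPM of at least 1, and the lowest number belonged to CBX_P1 replicate 21, which listed 90.5% of genes at 0.

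The libraries fell into 2 kinds by content of the small noncoding RNAs 7SK, a regulator of transcription elongation, and 7SL, the RNA of the signal recognition particle. In 18 libraries (14 CBX_P1, both CBX_P2 and 2 CCX_P1) these RNAs took 15.8 to 65.1% of TPM, with a median of 35.2%, and nuclear protein-coding genes took a median of 21.6%. In the other 46 (44 CBX_P1 and 2 CCX_P1) the share of 7SK and 7SL was 0.0346 to 1.10% and that of protein-coding genes a median of 83.2%. Recovered reads had a median of 5.43 M in the first kind and 23.2 M in the second. Within CBX_P1, 16058 of 26610 genes differed between the kinds in limma's test, 14988 of them lower in the libraries rich in 7SK and 7SL. On TPM rescaled over protein-coding genes 2621 of 17576 differed, 484 of them lower. The 2 kinds are called high-7SK and low-7SK libraries from here on, and values within each stand beside pooled ones.

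**Figure D1:**
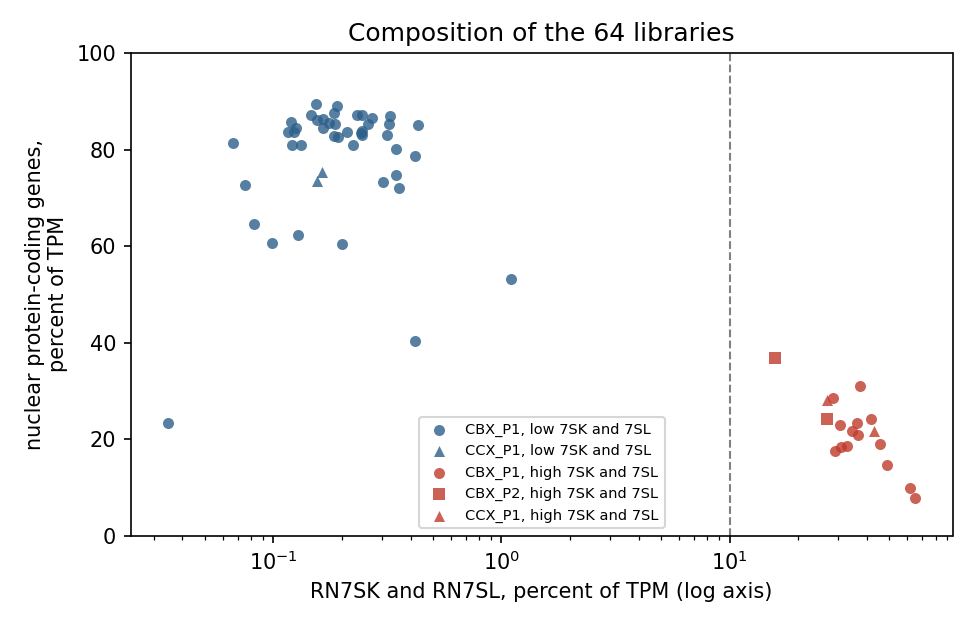
Each point is a library, with the share of TPM in RN7SK and RN7SL genes on a log axis in percent against the share in nuclear protein-coding genes in percent, coloured by kind and shaped by group, and a dashed line at 10%. The 18 libraries to the right of the line sit between 15.8 and 65.1%, and the 2 CBX_P2 libraries are among them.

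NEUROD1, a neurogenic transcription factor, had a median of 8.43 TPM (quartiles 1.11 and 48.4, n = 64) and reached 10 TPM in 31 tumours, with a maximum of 1249. POU2F3, the regulator of tuft cells, had a median of 0.28 and reached 10 TPM in 3 tumours, and ATOH1, a factor of secretory and sensory cells, had a median of 0 and did so in 2. YAP1, a coactivator of the Hippo pathway, had a median of 0.405 TPM and a maximum of 38.9. After rescaling, NEUROD1 reached 10 in 37 tumours, POU2F3 in 3 and ATOH1 in 2.

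The 3 tumours with POU2F3 at 10 TPM or more carried other tuft cell genes. Rescaled TPM was 25.7 to 386 for AVIL, an actin-binding protein, 13.7 to 40.7 for the transcription factor GFI1B and 3.02 to 107 for TRPM5, the taste and tuft cell channel. CHGA, a secretory granule protein, reached at most 0.972 and SYP, a synaptic vesicle protein, at most 4.93 in them, while 2 of the 3 held INSM1 (4.64 to 67.3) and NCAM1 (0.972 to 113), other neuroendocrine markers, at 10 or more. MYC was 216 to 431 there, against a median of 3.84 over all 64 tumours. In the 2 tumours with ATOH1 at 10 TPM or more, ATOH1 stood at 138 and 374 and CHGA at 130 and 991. These ranges describe tumours picked by their own expression and test nothing.

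Cell surface and treatment-related genes spanned wide ranges. In rescaled TPM, DLL3, a Notch ligand, had a median of 39.4 (quartiles 18.3 and 71.1) and reached 10 in 53 tumours. SEZ6, a neuronal surface protein, had a median of 77.4 and CD276, an immune checkpoint ligand, 48.6. SSTR2, a somatostatin receptor, had a median of 4.07, with 19 tumours at 10 or more. SLFN11, a replication stress factor, had a median of 43.1 and was below 10 in 13 tumours. Among the MYC genes, MYCL had a median of 47.3 and a maximum of 2816, MYC 3.84 and 1703, and MYCN 1.67 and 95.1. CDKN2A, a cell cycle inhibitor, was high, with a median of 307, and RB1 was low, with a median of 10.5. EPCAM had a median of 447 and VIM, a mesenchymal filament, 16.2. Unscaled TPM in CBX_P1 gave the same order of medians for MYCL, MYC and MYCN.

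Of the 500 most variable genes, 298 were ribosomal, histone, small RNA, mitochondrial or immunoglobulin V, D or J genes or had no symbol in the deposited table. Among those that could be named NNAT, an imprinted neuronal gene, led (SD 4.14 on the log2 scale, maximum 5822 TPM), followed by HLA-B (SD 3.87), GRP, which encodes gastrin-releasing peptide (SD 3.54), CD74, the HLA class II chaperone (SD 3.496), and JCHAIN, the joining chain of secreted antibody (SD 3.45). H19, MEG3, DLK1 and PEG10, also imprinted, and GHRH, FABP7, STMN2 and PRAME were among the 30 named genes of highest variance. HLA levels are uncertain, since reads of these polymorphic and similar genes can be lost or shared. Lists over-represented among the 500 most variable genes in a hypergeometric test were antigen presentation (8 of 12 members, among them HLA-B, TAP1, PSMB9, PSMB8 and NLRC5, adjusted p = 1.57e-10) and the neuroendocrine list (9 of 25, adjusted p = 3.26e-09). So were the epithelial list (5 of 12, adjusted p = 9.38e-06, but none of 12 with a pseudocount of 0.1), the non-neuroendocrine list (5 of 25, adjusted p = 0.000411) and the T and NK cell list (3 of 8, adjusted p = 0.00132).

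The first principal component held 37.9% of the variance (jackknife SE 3.53). Its score correlated with the proliferation list mean (r = -0.933, rho = -0.853), the chromatin regulator list mean (r = -0.918, rho = -0.921), the percentage of TPM in 7SK and 7SL (r = 0.833, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 5.36e-05 over 75 values, rho = 0.482) and the number of detected genes (r = -0.851, rho = -0.857). Within low-7SK and high-7SK libraries the r of the last 2 measures were 0.511 and 0.826, and -0.907 and -0.916. After rescaling, the first component held 16.4% and ran from SCNN1A, GRP and TFF3, to LCP1, RAC2 and IKZF1. Its score correlated with the neuroendocrine list mean (r = 0.716, rho = 0.571, adjusted p = 6.82e-05, and r = 0.787 within each kind), the proliferation list mean (r = 0.876, rho = 0.477) and the number of detected genes (r = 0.722, rho = 0.346, and r = 0.956 within low-7SK and 0.621 within high-7SK libraries). The sparse CBX_P1 replicate 21 entered these correlations and lay at a score of -400.9, with the next library at -97.2. The second component after rescaling (10.9%) was led by HLA-B, HLA-DRA, CD74 and JCHAIN, and correlated with the B cell list mean (r = 0.834, 0.839 within low-7SK and 0.833 within high-7SK libraries), the T and NK cell list mean (r = 0.830, 0.778 and 0.927) and the antigen presentation list mean (r = 0.809, 0.789 and 0.857).

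Transcripts of immune cells were abundant in a minority of first-passage tumours. Immunoglobulin genes took over 1% of TPM in 12 of 58 CBX_P1 tumours, with a maximum of 48.6%, and in none of the 2 CBX_P2 or 4 CCX_P1 tumours. IGKC, the kappa light chain constant gene, reached 1000 TPM in 14 tumours, IGHG1 in 11 and IGHA1 in 9, while CD79A, a B cell receptor component, reached 10 TPM in 11 and CD3D, a T cell receptor component, in 13. Among 45 low-7SK tumours the immunoglobulin share rose with the T and NK cell list mean (r = 0.874, rho = 0.797, both permutation p = 1e-05, the smallest the permutations can give, adjusted p = 4.5e-05 and 6e-05 over 18 values each, r = 0.850 without the 2 farthest tumours). The B cell list mean did so too (r = 0.850, rho = 0.534, permutation p = 0.00014 for rho). In 16 high-7SK tumours r was 0.921 with the T and NK cell list and 0.897 with the B cell list. With the fibroblast list mean r was -0.0623 in low-7SK tumours (rho = 0.0435, permutation p = 0.775), and in high-7SK tumours rho was 0.488 (permutation p = 0.0587, adjusted p = 0.0813). With the endothelial list mean rho was 0.345 in low-7SK (permutation p = 0.0207, adjusted p = 0.0415) and 0.509 in high-7SK tumours (permutation p = 0.0472, adjusted p = 0.0708). The macrophage list mean rose with the share by r (0.367 in low-7SK, permutation p = 0.0131, adjusted p = 0.0262, and 0.655 in high-7SK tumours, permutation p = 0.0154, adjusted p = 0.0277) but did not pass by rho (0.311 and 0.529, adjusted p = 0.0629 for both). Without the 2 farthest tumours these r were 0.157 and 0.00849. Maxima of the list means on the log2(rescaled TPM + 1) scale were 8.73 for T and NK cells, 7.44 for B cells, 5.90 for fibroblasts, 5.33 for macrophages, 3.28 for red cells, 2.78 for endothelial cells and 1.39 for hepatocytes.

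**Figure D2:**
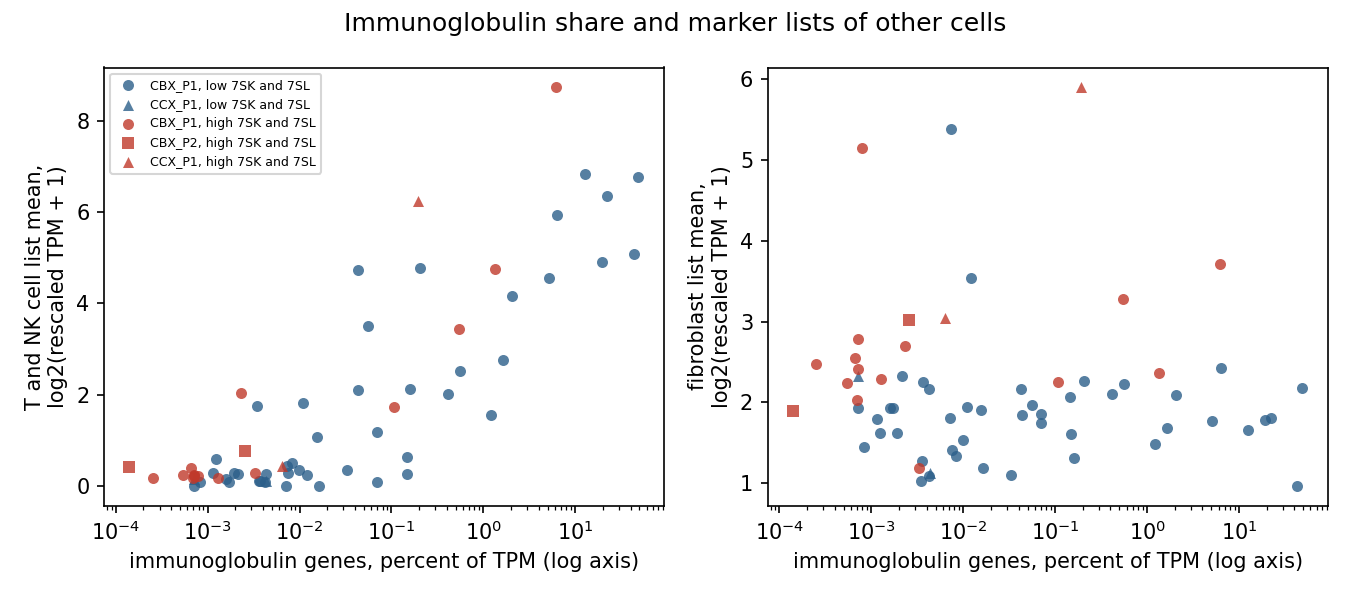
Each point is a tumour, with the share of TPM in immunoglobulin genes in percent on a log axis against the mean of the T and NK cell list (left) or the fibroblast list (right) as log2(rescaled TPM + 1), coloured by library kind and shaped by group. Among low-7SK tumours rho was 0.797 on the left and 0.0435 on the right.

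Of the 30 relations between measures fixed in advance, 9 held a value past the threshold, among 63 values computed because 28 relations had a clustered measure. The antigen presentation and interferon response lists rose together in 61 tumours (r = 0.875, rho = 0.863, both permutation p = 1e-05, the smallest possible, adjusted p = 0.000126 and 0.000157), with r of 0.885 in low-7SK and 0.807 in high-7SK libraries and 0.860 without the 2 farthest tumours. Both lists also rose with the immunoglobulin share in low-7SK tumours (r = 0.713 and 0.735, permutation tests, adjusted p = 4.5e-05 for both), so their relation was not separated from lymphocyte content. The proliferation list rose with EZH2, a histone methyltransferase, in both clusters (r = 0.626, rho = 0.675, n = 47, adjusted p = 0.000126, and r = 0.889, rho = 0.842, n = 14, adjusted p = 0.000315, permutation tests). After rescaling no cluster split this relation and r was 0.691 (0.705 in low-7SK and 0.676 in high-7SK libraries). Mesenchymal and fibroblast list means rose together (r = 0.590, rho = 0.557, n = 58, permutation p = 2e-05, adjusted p = 0.00018), also within low-7SK (r = 0.520) and high-7SK libraries (r = 0.897).

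Proliferation and hypoxia lists gave a pooled r of 0.749 (rho = 0.567, permutation p = 1e-05, adjusted p = 0.000126), 0.652 in high-7SK libraries and 0.0434 on rescaled TPM. In the 43 low-7SK tumours of the larger cluster r was -0.218 (permutation p = 0.161, adjusted p = 0.389). NEUROD1 did not pass with MYC or YAP1 in any cluster. In 23 tumours of 1 joint cluster NEUROD1 and MYC gave r = 0.233 (rho = 0.262, permutation p = 0.288, adjusted p = 0.491). After rescaling, 19 tumours of 1 joint cluster gave r = 0.564 (permutation p = 0.0106, adjusted p = 0.0716) and rho = 0.627 (permutation p = 0.00527, adjusted p = 0.0356), the latter past the threshold.

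REST, the repressor of neuronal genes, was lower where the neuroendocrine list was higher. On rescaled TPM r was -0.736 over 61 tumours (rho = -0.640, permutation p = 1e-05, adjusted p = 0.00018 over 54 values), with -0.712 in low-7SK libraries and -0.724 without the 2 farthest tumours. In high-7SK libraries the list mean was clustered, and the 14 tumours of the larger cluster gave r = -0.700, which did not pass (permutation p = 0.006, adjusted p = 0.0622). On unscaled TPM the list mean was clustered, and in the larger cluster of 34 tumours r was -0.372 and did not pass (rho = -0.347, permutation p = 0.0296, adjusted p = 0.124). The neuroendocrine and non-neuroendocrine lists gave r = -0.452 on rescaled TPM (rho = -0.387, permutation p = 0.00073, adjusted p = 0.00657), with -0.303 in low-7SK libraries and -0.596 in the 14 high-7SK tumours (permutation p = 0.0247, adjusted p = 0.113). On unscaled TPM they gave -0.134 (permutation p = 0.436, adjusted p = 0.639). Neuroendocrine and proliferation lists gave r = 0.680 in 34 tumours (permutation p = 2e-05, adjusted p = 0.00018, rho = 0.579), but 0.212 in the 18 low-7SK and 0.897 in the 16 high-7SK libraries among them. The neuroendocrine list also rose with the lung adenocarcinoma and alveolar list in those 34 tumours (r = 0.513, rho = 0.516, permutation p = 0.00299, adjusted p = 0.0188, and 0.430 after rescaling in 55 tumours). With the fibroblast list it gave r = 0.578 in 26 low-7SK tumours (rho = 0.577, permutation p = 0.00223, adjusted p = 0.0156) and -0.153 after rescaling in 55 tumours (permutation p = 0.265).

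**Figure D3:**
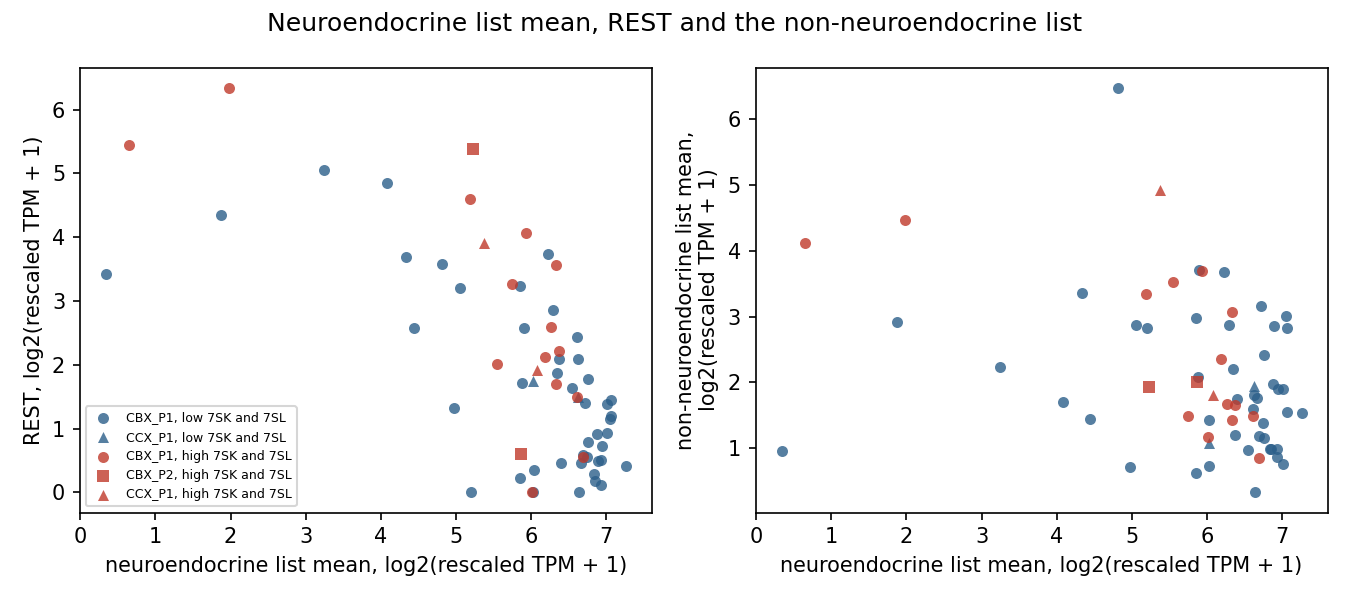
Each point is a tumour, with the mean of the neuroendocrine list on the horizontal axes against REST (left) and the mean of the non-neuroendocrine list (right), all as log2(rescaled TPM + 1), coloured by library kind and shaped by group. Over 61 of the 64 tumours drawn, r was -0.736 on the left and -0.452 on the right.

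INA, CPE and SNAP25 rose with the neuroendocrine list mean and REST fell. With library kind as a term on rescaled TPM (61 tumours), 3809 of 17550 genes passed in limma's test, 2702 rising with the mean and 1107 falling. The leading ones were INA, a neuronal filament (slope 0.99 ± 0.07 SE per unit of the mean), CPE, a prohormone-processing enzyme (1.22 ± 0.09), SNAP25, a vesicle fusion protein (1.05 ± 0.08), GNG4, RIMS2, ACTL6B and CHRNB2. Falling genes were led by CCDC102A (-0.66 ± 0.07) and REST (-0.84 ± 0.11, adjusted p = 2.78e-08). They included the myeloid genes LILRA2, GPR141, LRRC25, MARCO and LYZ and the stress ligand MICA. For these myeloid genes rho was -0.370 to -0.531. Within low-7SK and high-7SK libraries r was -0.428 and -0.959 for MARCO, -0.526 and -0.944 for LILRA2 and -0.555 and -0.915 for LRRC25. It was -0.674 and -0.737 for GPR141 and -0.642 and -0.706 for LYZ. The high-7SK library CBX_P1 replicate 29 had a list mean of 0.655 and the highest T and NK cell list mean (8.73). No fit on rescaled TPM left it out, so its weight in these slopes is unknown. Of the epithelial list 7 of 12 genes rose (7 adjusted over the list alone). Of the tuft cell list 7 of 10 fell (8 adjusted over the list alone), of the non-neuroendocrine list 9 of 25 fell (11 adjusted over the list alone), and of the macrophage list 6 of 8 fell (7 adjusted over the list alone). Antigen presentation had 1 of 12 fall and none adjusted over the list alone. These counts depended on the fit. Without rescaling, in the fit set in advance, 5 epithelial genes rose (5 adjusted over the list alone), while 1 tuft cell (0), 0 non-neuroendocrine (0) and 2 macrophage genes (2) fell. Library kind as a term on unscaled TPM gave 1 (1), 4 (6), 3 (3) and 2 (2) in the same order.

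Without rescaling, the list mean was clustered, and the larger cluster of 35 tumours held all 16 high-7SK tumours. In that fit, the one set in advance, 10484 of 26584 genes passed, 10281 rising and 203 falling. GNG4 (slope 1.36 ± 0.11), SNAP25 (1.204 ± 0.10), STMN3, INA, CAMK2N2 and CPE rose, and CHI3L1, MARCO, LYZ, SERPINA1, LAIR1 and IFI44L fell. By rank these falls were weaker, with rho from -0.0786 for LAIR1 and -0.255 for CHI3L1 to -0.440 for IFI44L, against r of -0.511, -0.643 and -0.491. All 12 proliferation genes and 7 of 12 hypoxia genes rose there (12 and 8 adjusted over the list alone), but 8 and 0 did on rescaled TPM with library kind as a term. With library kind as a term on unscaled TPM 3279 genes passed, and in 34 low-7SK tumours of the larger cluster 260 (251 rising, 9 falling), where the list mean spanned only 5.45 to 6.93. The split of rising against falling genes moved with scaling: 2321 to 1192 after rescaling alone, 2407 to 2356 after quantile normalisation, 1649 to 2276 after median-of-ratios scaling and 1712 to 2238 in the log counts.

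Tumours that shared a prefix and a label number were not more alike than other tumours in the test set in advance. The 3 pairs correlated across genes at 0.876, 0.846 and 0.484, a mean of 0.735, against a median of 0.8288 over all 2016 pairs (one-sided permutation p = 0.889 from 100000 draws of 3 pairs). The lowest value belonged to the pair with the sparse CBX_P1 replicate 21. Without that library the mean of the other 2 pairs was 0.860 (permutation p = 0.227). Both of these pairs joined a low-7SK with a high-7SK library. The test on unscaled TPM therefore mixed likeness of tumours with library kind and cannot decide whether such tumours are alike. On rescaled TPM these 2 pairs correlated at 0.959 and 0.924, and their mean of 0.941 exceeded nearly all draws (permutation p = 0.00014). Genes are not independent replicates, so these correlations describe library similarity.

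In the fit of all tumours, the 2 second-passage tumours had higher levels of the transcription factor SOX6, the Hippo pathway kinase LATS2 and the ephrin receptor EPHA4. SOX6 (ENSG00000110693) stood at 57.2 and 68.2 TPM, above all 58 first-passage CBX tumours (median 4.04, maximum 29.3; log2 change 3.83 ± 0.88 SE, limma adjusted p = 0.00342). LATS2, picked in the rescaled fit, stood at 2.60 and 5.38 TPM against at most 2 (log2 change 1.86 ± 0.31, adjusted p = 2.76e-05). EPHA4 was at 34.9 and 124 TPM against a median of 5.96, with 1 first-passage tumour at or above the lower value (log2 change 3.33 ± 0.95, adjusted p = 0.0342). Among noncoding genes, the imprinted MEG8 rose (log2 change 5.51 ± 1.42, adjusted p = 0.0139), with 4 first-passage tumours at or above the lower second-passage value, as did the pseudogene EMBP1 (log2 change 3.40 ± 0.53, adjusted p = 7.44e-06), whose reads can be shared with EMB. SNHG9, a small nucleolar RNA host gene, was listed at 0 in both (first-passage median 41.3 TPM). PATZ1, a transcriptional repressor, fell by 3.44 ± 0.91 (adjusted p = 0.0163), and DRG1, ZNF593 and the respiratory complex I subunit NDUFS4 also fell.

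In all, 696 of 26610 genes differed between passages, 682 higher and 14 lower, and 2621 had an unadjusted p below 0.05. Leaving out either second-passage tumour ended the call of 11 of the 16 genes picked by the rule for naming, SOX6 and EPHA4 among them, and leaving out replicate 1 reversed 1 more. The counts were then 373 and 977 genes. Among 100 splits of the 16 high-7SK CBX libraries into 2 against 14, the real one included, 5 called at least the 438 genes of the real split in its own fit. Chance is therefore not excluded. Of the 696 calls in the fit of all tumours, 252 were long noncoding RNAs, 222 pseudogenes, 83 small RNAs and 80 protein-coding genes. In 234 of the 696 the first-passage mean was below 0.1 on the log2 scale, near the floor. Both second-passage libraries were high-7SK. With library kind as a term 633 genes passed, 536 of them shared with the 696, while 164 of the 696 passed in the fit within high-7SK libraries. With the term, EPHA4 and SOX6 still passed (adjusted p = 0.0235 and 0.0123). MEG8 kept most of its change without passing (4.77 ± 1.47, adjusted p = 0.068). The changes of PATZ1 (-1.86 ± 0.67, adjusted p = 0.164), DRG1 (-1.30 ± 0.59, adjusted p = 0.353), ZNF593 (-1.16 ± 0.53, adjusted p = 0.36) and NDUFS4 (-1.15 ± 0.51, adjusted p = 0.346) shrank and did not pass. On rescaled TPM with library kind as a term 117 of 17576 protein-coding genes passed (108 higher, 9 lower), 45 of them among the 80 called genes that this table holds. LATS2 (2.49 ± 0.55), CCDC152 (4.32 ± 0.81) and HHIP, a hedgehog-binding protein (3.64 ± 0.90), were higher there. PATZ1 (-3.31 ± 0.57), DRG1 (-2.88 ± 0.58), ZNF593 (-2.37 ± 0.60) and NDUFS4 (-1.85 ± 0.45) were lower in that fit. SOX6 (adjusted p = 0.0785) and EPHA4 (adjusted p = 0.153) did not pass in it. Unscaled TPM of the 2 second-passage tumours was 0 and 29.96 for DRG1, 0 and 7.7 for ZNF593 and 0.07 and 9.06 for PATZ1. Medians of the high-7SK first-passage CBX tumours were 13.08, 5.235 and 10.69, so these falls rest mainly on the lower value. NDUFS4, at 3.63 and 10.6, was below its median there in both. In high-7SK libraries only, rescaled, 13 genes passed. The split of higher against lower calls was 57 to 70 in the log counts, 266 to 51 after rescaling, 825 to 219 after quantile normalisation and 1120 to 157 after median-of-ratios scaling.

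Camera called 2 of the 23 lists between passages, and neither passed with an estimated correlation (adjusted p = 0.992 for both). With library kind as a term the adjusted p was 0.187 for the squamous list and 0.000112 for the interferon response list (0.772 for both with an estimated correlation), and in the log counts 0.0783 and 0.146. On rescaled TPM with that term both were called (0.0382 and 6.92e-05), and neither with an estimated correlation (adjusted p = 0.913 for both). TP63, a squamous lineage factor, rose (log2 change 2.71 ± 0.56, adjusted p = 0.000921), 1 of 9 squamous genes by either adjustment (1 adjusted over the list alone), and camera called the squamous list higher (median log2 change 0.90, adjusted p = 0.038). The second-passage SD of TP63 was 4.36 (n = 2), so the 2 tumours lay far apart. On rescaled TPM with library kind as a term, and in the log counts, 0 of 9 squamous genes passed over all genes. Adjusted over the list alone, 1 passed in each. Camera also called the interferon response list lower (median log2 change -1.60, adjusted p = 0.038), though none of its 12 genes passed, also none adjusted over the list alone. IFI27 stood at a mean of 0.66 against 4.92 (adjusted p = 0.412). Antigen presentation had a median log2 change of -2.38 (adjusted p = 0.0709), T and NK cell markers -1.29 (adjusted p = 0.696) and fibroblast markers -0.11 (adjusted p = 0.929), with a median of -0.23 over all genes. Camera with library kind as a term also called antigen presentation (median log2 change -0.82, adjusted p = 0.0112) and T and NK cell markers (-0.82, adjusted p = 0.0425) lower, and neither passed with an estimated correlation (adjusted p = 0.772 for both). The interferon response list was therefore not separated from lymphocyte content.

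The 4 CCX tumours differed from first-passage CBX tumours in few genes. Those higher included KRT20, an intestinal and Merkel cell keratin (log2 change 2.09 ± 0.43 SE, limma adjusted p = 0.0145), the heparan sulfate sulfotransferase HS3ST3A1 (1.99 ± 0.43, adjusted p = 0.0346), the polycystin-like genes PKD1L3 (1.76 ± 0.32) and PKD1L2 (1.29 ± 0.24), the adaptor SHE (1.71 ± 0.32), TDRD10 (1.09 ± 0.19) and HAS2, a hyaluronan synthase (0.76 ± 0.16). KRT20 ranged from 0 to 122 TPM in the 4 tumours. Over all 26610 genes 17 passed, all higher, and 955 had an unadjusted p below 0.05. All 7 of these genes ended their call without CCX_P1 replicate 2, although 13 genes passed then. Without replicates 1, 3 and 4 in turn, 65, 91 and 89 passed. With library kind as a term 40 passed, and on rescaled TPM with that term 14 did, 6 of them among the 17.

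Of the lists, camera called fibroblast markers higher in CCX tumours (median log2 change 0.54, adjusted p = 0.0029), with 0 of 9 genes past the threshold over all genes and 3 adjusted over the list alone. On rescaled TPM the list mean was 1.13, 2.33, 3.04 and 5.90 in CCX_P1 replicates 1 to 4 (median over all 64 tumours 1.93). Replicate 4 held the highest value of all 64, and the list was not tested without it. LUM (log2 change 2.75 ± 0.63, adjusted p = 0.0611) and DCN (2.44 ± 0.81, adjusted p = 0.481), both matrix proteoglycans, did not pass over all genes, and COL1A2 was at -1.86 ± 1.001. LUM passed with library kind as a term (2.87, adjusted p = 0.0301) and on rescaled TPM with that term (3.62 ± 0.72, adjusted p = 0.00798). With an estimated correlation the list did not pass (adjusted p = 0.384). Of 100 splits of the tumours, the real one included, 43 called at least as many genes as the 17. The splits were drawn without regard to library kind, while the CCX tumours held 2 of each kind. They therefore cannot say how many calls chance gives at that balance. The labels give no meaning for the 2 prefixes, so chance, a batch and a biological difference cannot be told apart here.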

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

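The rule for a tumour far from its group was set in advance: the gap to the nearest other value, divided by the group's range, had to exceed Dixon's 95% critical value. Only the 4 CCX_P1 tumours form a group of a size that it covers, and chance alone meets it in about 1 in 20 of the 53 measures tested there. In CCX_P1 replicate 2, ATOH1 stood at log2(TPM + 1) of 8.14 against 0 in the other 3 tumours, a gap ratio of 1. CCX_P1 replicate 4 had VIM, a mesenchymal filament gene, at 7.81 against 3.77 in the nearest tumour, a ratio of 0.836. Its T and NK cell list mean was 4.13 against 0.164 in the nearest, a ratio of 0.978. No explanation of these 3 values was tested.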

How the results depend on the processing

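Fits with library kind as a term, within 1 kind or on rescaled TPM, limma-voom fits and fits without the sparse library were chosen after seeing the data. No paired analysis was possible because all tumours carry the same replicate number in the labels and the groups compared share only 1 title number.

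The passage count (696) was 339 with a pseudocount of 0.1, 4639 with no filter, 139 with TPM of 1 in 6 libraries, 127 in the log counts, 1277 with median-of-ratios scaling, 1044 after quantile normalisation and 317 on rescaled TPM. It was 633 with library kind as a term, 431 in high-7SK libraries, 117 on rescaled TPM with that term, 13 on rescaled TPM in high-7SK libraries and 102 with voom. It stayed between 693 and 726 with robust moderation, 1 tumour per number, a fibroblast covariate, only the 2 groups or no sparse library. Leaving out a second-passage replicate gave 373 and 977, with the lone tumour assumed to vary like the others.

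The CCX count (17) was 6 with a pseudocount of 0.1, 696 with no filter, 5 with TPM of 1 in 6 libraries, 3 in the log counts, 52 with median-of-ratios scaling, 40 with library kind as a term, 30 in high-7SK and 239 in low-7SK libraries, 7 on rescaled TPM in high-7SK libraries and 269 with voom. Leaving out a CCX replicate gave 13 to 91. The filters test fewer or more genes near the floor. The cause of the other shifts was not tested.

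The neuroendocrine count (10484) was 16392 with a pseudocount of 0.1, 3950 in the log counts, 4763 after quantile normalisation, 3925 with median-of-ratios scaling, 3513 on rescaled TPM, 15755 in CBX_P1 only, 3279 with library kind as a term, 260 in low-7SK and 3517 in high-7SK libraries and 3809 on rescaled TPM with that term. In several of these the list mean was no longer clustered, so up to 61 tumours entered. It was 9408 to 12008 with the other filters, robust moderation, all 64 tumours or a fibroblast covariate.

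Of 46 list tests camera called 4, against 0 with an estimated correlation, 6 in the log counts, 10 with library kind as a term and 7 on rescaled TPM with that term. Relations with a call numbered 9, against 13 with a pseudocount of 0.1, 12 in the log counts, 7 on rescaled TPM, 2 on rescaled TPM in high-7SK and 5 in low-7SK libraries. The first component held 17.5% in the log counts, 41.7% of the 500 most variable genes and 16.4% on rescaled TPM. The mean r of pairs that share a number was 0.941 on rescaled TPM without the sparse library.

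Reversed values were the r of proliferation with hypoxia (-0.0543 in the larger cluster of CBX_P1 only, -0.0714 in the log counts and -0.218 in the larger cluster of low-7SK libraries) and PIK3R3 between passages (-0.46 in the log counts and -0.69 with voom, which hold the symbol's other identifier, and -0.44 without CBX_P2 replicate 1, against 6.76 without replicate 2). In low-7SK libraries the slopes on the neuroendocrine mean reversed for SLC35G2 (-0.11), TMEM145 (-1.04), SEZ6L2 (-0.0043), POTEF (0.0905), TSPAN32 (0.21), PIRT (0.48), LAIR1 (0.0816), C11orf21 (0.21) and DAB2 (0.20). The cause was not tested. Of the values for named genes in alternatives, 320 in the neuroendocrine fit, 106 in the CCX fit and 186 in the passage fit kept their direction and side of the threshold, while 26, 41 and 97 lost the call and 9, 0 and 3 reversed. With 1.86 M reads in the shallower second-passage library, low genes there rest on few reads.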

Other observations

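The tests of library kind, other splits, immunoglobulin and stroma below were chosen after the results were seen, and the chi-square test of the closest pair before. DEFA6 and DEFA5, defensins of intestinal Paneth cells, reached 108700 and 14630 rescaled TPM at their maximum, and each was at or above 1000 in 1 tumour, with a median of 0. PAX5, a B cell factor, had a median of 10.8 rescaled TPM over all 64 tumours, while MS4A1, which encodes the B cell antigen CD20, had a median of 0 TPM.

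Second-passage calls (SOX6, LATS2, PATZ1 and others) were set against library kind and chance. With library kind as a term on rescaled TPM, 117 genes passed. That number cannot be set against 696, since the rescaled table holds only 80 of those 696 genes, of which 45 passed. With the term alone 536 of the 696 passed, and within high-7SK libraries 164 did. The part owed to library kind stays open, since both second-passage libraries are of 1 kind. Among 100 splits of the 16 high-7SK CBX libraries into 2 against 14, the real one included, 5 called at least the 438 genes of the real split in its own fit. The highest other split called 4162. Chance therefore remains an explanation, and a change with passage was not tested apart from it. Of 100 splits for the CCX comparison, the real one included, 43 called at least 17 genes, and the highest other called 6317. Those splits ignored library kind, so they do not measure chance at the CCX balance of kinds. Chance remains an explanation there too.

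Immunoglobulin genes were abundant in 12 first-passage CBX tumours. Their share rose with T and NK cell markers in low-7SK tumours (rho = 0.797), consistent with human lymphocytes and plasma cells carried over in the grafts or growing in the mice, as a hypothesis found and tested on the same data. Shares above 1% were not confined to 1 kind of library. They occurred in 2 high-7SK and 10 low-7SK libraries, against 16 and 36 at or under 1% (Fisher's exact test, p = 0.483). The share is a percentage of TPM, and abundant noncoding RNAs take much of the TPM in high-7SK libraries. A cut of 1% is therefore not comparable between the kinds, and the part owed to library kind stays open. In low-7SK tumours the fibroblast list mean did not rise with the share (rho = 0.0435). The tumours grew in mice and the handling of mouse reads is not given. This list of human genes may therefore not measure stroma, and its value cannot decide on it. The endothelial list mean did rise in low-7SK tumours by rank (rho = 0.345, permutation p = 0.0207, adjusted p = 0.0415). In high-7SK tumours the fibroblast and endothelial values of rho were 0.488 (adjusted p = 0.0813) and 0.509 (adjusted p = 0.0708). Stroma therefore stays open as an explanation in both kinds of library. Mouse reads and an expression by the tumour cells themselves were not tested.

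On rescaled TPM, 1 pair of libraries with different label numbers was more alike than any pair that shares one (r = 0.981). On unscaled TPM 490 pairs exceeded the highest pair that shares a number, a low-7SK with a high-7SK library, so the finding does not hold on that scale. In the log counts, as on rescaled TPM, exactly 1 pair exceeded the highest pair that shares a number (r = 0.989 against 0.967). Both libraries were high-7SK. The chi-square of their recovered reads was 7.24 per degree of freedom over 14532 genes, above the sampling noise that the same library deposited again would show. The other 19 closest pairs gave 86.0 to 237, but each held a low-7SK library. Low-7SK libraries had a median of 23.2 M reads against 5.43 M in high-7SK libraries. The values were not adjusted for depth or kind, so this contrast does not measure likeness alone. Separate libraries of the same tumour or patient were not tested, and both were kept as separate tumours.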
